A study of Mus musculus with 2 samples.

How the data were processed

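Single-cell libraries of sorted CD45+ liver cells from 2 gates, 1 library each, were analysed from gene by cell matrices of UMI counts deposited by the authors. The values are raw, unnormalised counts, whole numbers summing to different totals per cell, and the matrices hold software version 3.0.1, per the file headers. STAR, Seurat 2.3.0 and the genome build GRCm38 are named per the submitters' processing notes, with no role or order. How the authors chose the barcodes in the matrices is not given in the sources used here. The lowest UMI total of a deposited barcode was 505 in the LSM library and 500 in the CD122+CD49a+ library. Both matrices list 27998 genes in the same order, and 27645 (98.7%) of the gene identifiers were found in GENCODE release M21 of GRCm38, from which gene types and positions were taken. The groups come from the sample labels. The libraries shared 3 barcodes.

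Cells with at least 500 detected genes and at most 10% mitochondrial UMIs were kept. In the LSM library 59 barcodes fell under the gene minimum and 9 over the mitochondrial limit. In the CD122+CD49a+ library 398 barcodes (24.0%) fell under the gene minimum and 9 over the mitochondrial limit. Doublets were scored with Scrublet in scanpy 1.11.5 at an expected rate of 0.8% per 1000 barcodes. Its automatic threshold marked 0.351% and 0.181% of barcodes, below the 0.5% set as the least acceptable, so the expected share with the highest scores was removed, 78 further LSM and 20 further CD122+CD49a+ cells.

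Each library was clustered on its own. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes were reduced to 20 principal components, and a graph of 15 nearest neighbours weighted by shared neighbours was partitioned by Leiden clustering at resolution 0.6 (leidenalg 0.10.2, igraph 0.11.9, scikit-learn 1.9.0). A marker was raised when it had a UMI in 10% of the cluster's cells and was at least 2-fold above the other cells, with a pseudocount of 5 CPM. Of the lists with at least 3 raised markers, the one with the largest raised share was tried, and the cluster was called like that cell type unless another list had more genes among its 10 leading genes. The markers shared by NK cells and ILC1 named no cluster by themselves but counted as another list. A cluster whose median UMI count was below the third part of its library's, with no marker of that type among its leading genes, stayed unnamed. Leading genes are those with the largest fold among genes with a UMI in 25% or more of the cluster's cells. The 25 marker lists and 13 gene groups were fixed before the data were examined. Of their 275 genes, 5 (T cell receptor and immunoglobulin constant genes) had no row and were not analysed here.

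Ratios between the libraries are of summed UMI counts scaled to the library's total and given as CPM, with exact conditional intervals for counting error. A count of 0 was set at a floor of 3 counts in that library, which equals 0.193 CPM in the LSM library and 1.30 CPM in the CD122+CD49a+ library, and its ratio is a bound. No test across samples was possible with 1 library per group. A list's median log2 ratio was taken over members with at least 20 UMIs in both libraries together and set against 10000 random lists of the same size matched on mean expression in 20 bins. The counting interval of a list median came from 200 Poisson draws. The named genes were fixed by rule before the data were examined: the 12 protein-coding genes with the largest ratio in each direction among those with at least 100 CPM in the higher library, 8 in each direction between the lymphocyte clusters with at least 100 CPM and 30 UMIs, up to 5 leading genes per cluster, and members of the fixed lists. Mitochondrial, ribosomal protein, numbered predicted, immunoglobulin and T cell receptor segment genes were left out of the ranking. Tyrobp, Fcer1g and Cd8b1 were added after the data were seen. Some genes that the rule names are not reported here.

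Because the LSM library was deeper, shares of cells with a UMI were compared after each cell was thinned to 1500 UMIs, leaving out shallower cells. Shares carry exact Clopper-Pearson intervals, and the limit beside a share of 0 is 3 counts divided by the cells, not the bound of that interval. Free RNA in droplets gives UMIs in cells that do not express a gene, so shares in clusters that should lack the gene are given beside them. Counting depth limits each library differently: a gene with 0 counts is bounded at a lower CPM in the LSM library.

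The procedures were tested on simulated data. Counts were drawn from a Poisson model for the real genes at the libraries' own depths, with 200 of 11365 genes changed. The intervals assume the same model, so their coverage does not show how they hold for UMIs that clump within cells. The 95% interval covered the true ratio of 96.3% of unchanged genes, 96% of genes raised 2-fold and 98% of genes raised 4-fold. Of 200 unchanged lists, 6.5% fell outside the central 95% of random lists. Of 450 simulated cells of 3 types, 100% fell into a cluster of their own type. The types were made from the mean profiles of the largest DC-like, the lymphoid progenitor-like and the monocyte-like LSM clusters, at LSM depths. Closer cell types and the shallower CD122+CD49a+ library were not simulated for clustering.

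Alternatives set before the data were examined were all barcodes without a filter, predicted doublets kept, TMM scaling (edgeR 4.0.16, R 4.3.3), a mean over cells of per-cell CPM, no low-count filter, a stricter cell filter of 1000 genes and 5% mitochondrial UMIs, Leiden resolutions 0.3 and 1.0, variable genes without cell cycle genes and those correlated with them above 0.3, joint clustering without integration, and thinning to 1000 UMIs or none. A minimum of 300 genes, a second clustering of clusters 1 and 3 of the CD122+CD49a+ library, the lymphocyte comparison against cluster 3 alone and list medians without the genes of the sort were added after the data were seen. Analyses used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.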

Results

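The study sorted CD45+ cells from the livers of C57BL/6 mice aged 7 to 10 weeks through 2 gates and profiled each by droplet single-cell RNA sequencing. The gate called LSM took lineage-negative cells with Sca-1 and Mac-1 on the surface, and the CD122+CD49a+ gate took lineage-negative cells with the interleukin-2 receptor beta chain (CD122) and integrin alpha 1 (CD49a), a pair of surface proteins known from liver-resident innate lymphocytes. There was 1 library per gate, so no difference between them has a replicate check, and no p-value is given. The LSM matrix held 3133 barcodes and 16226070 unique molecular identifiers (UMIs), with a median of 5032 UMIs per barcode. The CD122+CD49a+ matrix held 1655 barcodes and 2632303 UMIs, with a median of 1215. After filters, 2987 LSM cells (median 5059 UMIs) and 1228 CD122+CD49a+ cells (median 1457 UMIs) remained. All intervals are exact 95% intervals and cover counting error only; for a share of 0, the limit given is 3 counts of the cells. Gene positions are those of GRCm38.

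The comparison within the LSM library asked which blood cell types the gate held, heterogeneity of progenitors being the series' stated subject. Progenitor-like cells made up 2 of its 15 clusters. Cluster 2, lymphoid progenitor-like, held 523 cells or 17.5% (16.2 to 18.9), and cluster 13, stem and multipotent progenitor-like, held 50 cells or 1.67% (1.24 to 2.20). The largest cluster, cluster 1, was conventional dendritic cell (DC)-like with 613 cells or 20.5% (19.1 to 22.0). The other named clusters were myeloid, plasma cell, T cell and mast cell or basophil-like.

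Cluster 2 of the LSM library had 5 of 7 lymphoid progenitor markers raised, namely Flt3, a cytokine receptor of early progenitors, Dntt, the template-independent DNA polymerase of antigen receptor joining, Satb1, Notch1 and Il7r, the receptor of interleukin-7. Its leading genes were Wfdc18, Prss2, Nrgn, Tmem108 and Il12a. It also had 4 of 10 stem cell markers raised (Cd34, Kit, Meis1 and Hlf). Cd34 had a UMI in 61.8% (57.4 to 65.9) of cluster 2 cells, Flt3 in 51.2% (46.9 to 55.6), Dntt in 36.7% (32.6 to 41.0) and Il7r in 23.5% (19.9 to 27.4). In the monocyte-like cluster 4, taken as background, Cd34 had a UMI in 0.917% of cells, Flt3 in 0.306%, and Dntt and Il7r in 0 of 327 cells, which allows up to 0.917%. The median depth was 4751 UMIs in cluster 2 and 2344 in cluster 4. Rag1, part of the recombinase of antigen receptor genes, had a UMI in 5 of 523 cells of cluster 2 and 0 of 327 cells of cluster 4.

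Cluster 13 of the LSM library had all 10 stem and multipotent progenitor markers raised, among them Mecom, Procr, Gata2 and Hlf, and its leading genes included Prtn3, Angpt1, Snx14 and Ctla2a. It also had 3 of 8 granulocyte-monocyte progenitor markers raised (Mpo, Prtn3 and Gfi1). Cd34 had a UMI in 80.0% (66.3 to 90.0) of its cells, Kit in 60.0% (45.2 to 73.6) and Hlf in 48.0% (33.7 to 62.6). Il7r had a UMI in 0 of 50 cells, which allows up to 6.0%. In the monocyte-like cluster 4, Kit and Hlf had a UMI in 0 of 327 cells, and the median depth was 5134 UMIs in cluster 13 and 2344 in cluster 4. At Leiden resolution 0.3 and in the joint clustering of both libraries, neither progenitor cluster kept its name.

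The other named LSM clusters were monocyte-like cluster 4 (327 cells, 10.9%), led by Ace, Cd300e and Fabp4, conventional DC-like cluster 6 (163 cells, 5.46%), led by Fscn1, Apol7c and Ccr7, and plasmacytoid DC-like cluster 7 (159 cells, 5.32%), with 7 of 7 markers raised. Mast cell and basophil-like cluster 9 (123 cells, 4.12%) had 6 of 7 markers raised, including Cpa3 and Ms4a2. T cell-like cluster 10 (81 cells, 2.71%) was led by Gzma, Cd3g and Cd3d, plasma cell-like cluster 12 (73 cells, 2.44%) by Jchain and Mzb1, and Kupffer cell and macrophage-like cluster 14 (43 cells, 1.44%) by C1qa, C1qb and C1qc. The 5 unnamed clusters held 832 cells or 27.9% (26.3 to 29.5). Of these, cluster 3 (408 cells) was led by Rab7b and Cxx1b. It had 2 of 9 conventional DC markers raised (Clec9a and Xcr1), fewer than the 3 needed for a name. Its leading genes Rab7b, Cxx1a, Ppt1 and Gcsam were also leading genes of the conventional DC-like cluster 4 of the CD122+CD49a+ library. By the rule it is not counted in the conventional DC-like share of clusters 1 and 6. That share may thus leave out DC-like cells. Cluster 5 (170 cells) was led by Cxcl9, Ccl17 and Serpina3g and cluster 8 (152 cells) by Ly6c2 and Cd209d. Cluster 11 (79 cells) was led by Birc5, Ube2c and Nusap1, and cluster 15 (23 cells) by Abca9 and Adam15. The share of conventional DC-like cells depended on the setting: it was 26.0% (24.4 to 27.6) for clusters 1 and 6 together and 5.46% at Leiden resolution 1.0, where only 163 cells kept the name. With at least 1000 genes and at most 5% mitochondrial UMIs per cell, the T cell-like share was 0.973%, the monocyte-like share 6.89% and the Kupffer cell and macrophage-like share 0.856%. The plasmacytoid DC-like share was 9.61% in the joint clustering. There, 126 of the 152 cells of unnamed cluster 8 fell into a joint cluster with that name. With predicted doublets kept, 25 cells (0.816%) were ILC precursor-like, a name that no LSM cluster had at the other settings.

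**Figure D1:**
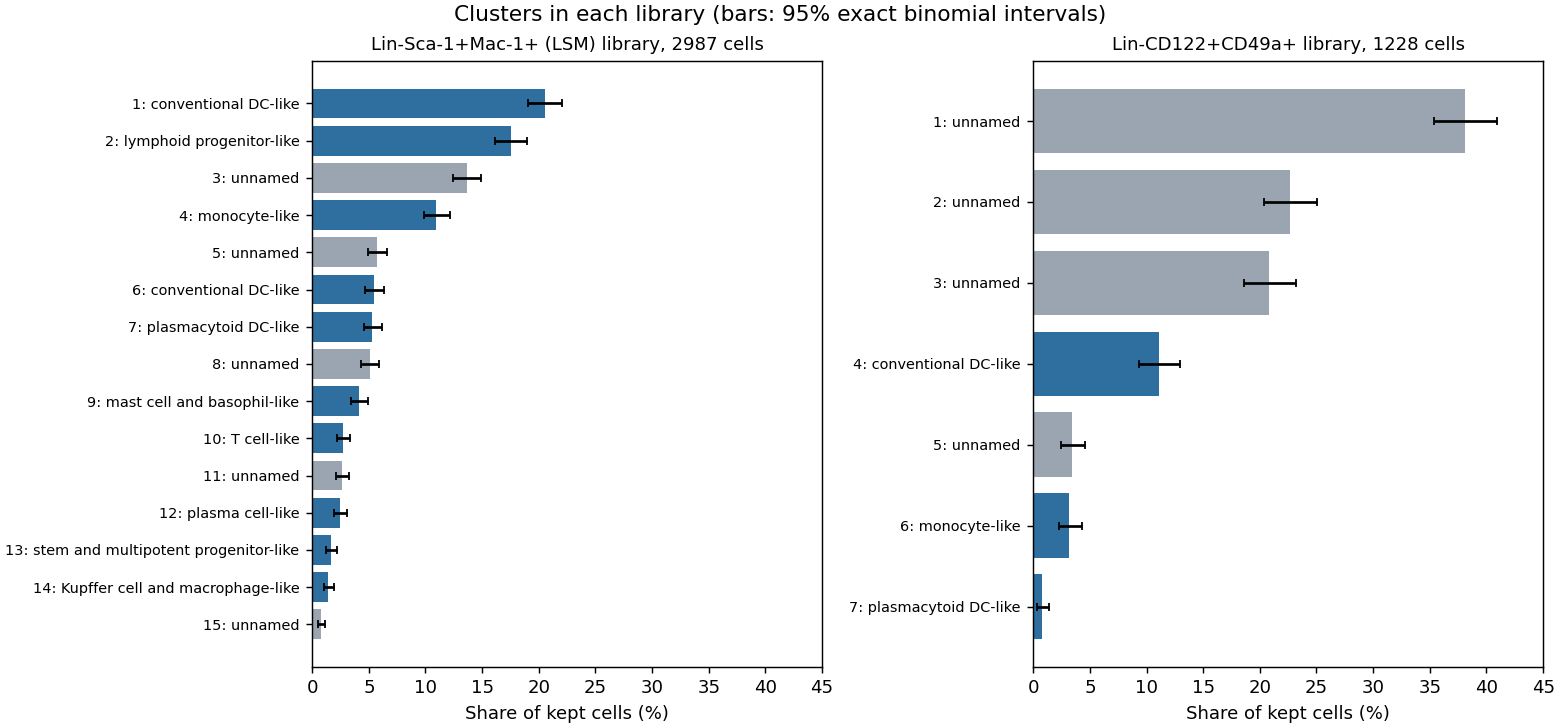
Share of kept cells in each cluster (percent, horizontal axis) of the LSM library (left) and the CD122+CD49a+ library (right); bars are shares, whiskers exact 95% binomial intervals, blue bars clusters named from fixed markers and grey bars unnamed clusters. LSM cluster 2, lymphoid progenitor-like, held 17.5% of cells, and unnamed cluster 1 of the CD122+CD49a+ library held 38.1%.

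Gene groups fixed before the data were examined differed between the LSM clusters. The 12 proliferation genes summed to 5773 CPM (UMI counts scaled to the total of the cluster; 5607 to 5943) in cluster 11, 1212 CPM (1087 to 1347) in the stem-like cluster 13 and 895 CPM (859 to 932) in the lymphoid progenitor-like cluster 2, against 103 CPM (92.4 to 114) in the DC-like cluster 1. The 12 interferon-stimulated genes summed to 6384 CPM (6244 to 6527) in cluster 5, which was itself partly defined by their members Cxcl9, Cxcl10 and Gbp2, and to 555 CPM (531 to 580) in cluster 1. The 7 MHC class II genes, which present peptides to CD4 T cells, summed to 51261 CPM (51034 to 51489) in cluster 1, 2916 CPM (2852 to 2982) in cluster 2 and 446 CPM (372 to 532) in cluster 13. The 10 dissociation and immediate early genes reached 33713 CPM (32989 to 34448) in the mast cell and basophil-like cluster 9 and 9529 CPM (9412 to 9646) in cluster 2.

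In the CD122+CD49a+ library, lymphocytes with T cell receptor complex transcripts were the main population, and DC-like and monocyte-like cells were the next. Cluster 1 held 468 cells or 38.1% (35.4 to 40.9) and cluster 3 held 256 cells or 20.8% (18.6 to 23.2). Cluster 2 held 278 cells or 22.6% (20.3 to 25.1), conventional DC-like cluster 4 held 136 cells or 11.1% (9.37 to 13), and monocyte-like cluster 6 held 39 cells or 3.18% (2.27 to 4.32). Proliferating cluster 5 (42 cells, 3.42%) was led by Hist1h2ap and Top2a, and plasmacytoid DC-like cluster 7 held 9 cells (0.733%). At this setting no cluster of the library passed the naming rule for ILC1, NK cells or T cells. In clusters 1 and 3 the T cell list had the largest share of raised markers among the lists that can name a cluster, but another list had more genes among the 10 leading genes. At Leiden resolution 1.0, ILC1-like cells made up 19.1% and T cell-like cells 34.6% of the library, and the T cell-like share was 16.8% without cell cycle genes and 59.2% in the joint clustering.

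Cluster 1 of the CD122+CD49a+ library was led by Maf, Ccnd2, Cxcr6, Il2rb and Zap70. It had 4 of 6 T cell markers raised (Cd3d, Cd3e, Cd3g and Cd4), 3 of 7 ILC1 markers (Cxcr6, Inpp4b and Cd160) and 5 of 10 markers shared by NK cells and ILC1 (Klrb1c, Nkg7, Tbx21, Il2rb and Xcl1). Cluster 3 was led by Cd8b1, Klra7, Cd8a, Gzma and Ccl5 and had 3 of 6 T cell markers and 7 of 10 shared NK and ILC1 markers raised. Cd3e, a chain of the T cell receptor complex, had a UMI in 59.6% (55.0 to 64.1) of cluster 1 and 48.0% (41.8 to 54.4) of cluster 3 cells. In clusters 2, 4 and 6 together, whose cells should lack it, the share was 0.883% (0.241 to 2.25). Ncr1, the NKp46 receptor of NK cells and ILC1, had a UMI in 0.641% (0.132 to 1.86) of cluster 1 cells and 2.34% (0.865 to 5.03) of cluster 3 cells, and in 11.9% (3.98 to 25.6) of the 42 proliferating cells of cluster 5. In clusters 2, 4 and 6 it had a UMI in 0 of 453 cells, which allows up to 0.662%. Tyrobp, a signalling adaptor of NK and myeloid cells that was looked at after its values were seen, had a UMI in 5.77% (3.84 to 8.28) of cluster 1 and 35.2% (29.3 to 41.3) of cluster 3 cells. In clusters 2, 4 and 6 it had a UMI in 92.9% of cells thinned to 1500 UMIs. Free RNA may thus give a low share such as that of cluster 1. The median depth was 1258 UMIs in clusters 1 and 3 together and 2192 in clusters 2, 4 and 6.

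Cluster 2 of the CD122+CD49a+ library was led by Cd209a, Clec10a, Wfdc17, Ms4a4c and Ccl9. It had 5 of 10 monocyte markers (such as Ccr2 and Csf1r) and 4 of 9 conventional DC markers (such as Cd209a and Itgax) raised. It stayed unnamed because the monocyte list, which had the larger raised share, had 0 genes among the 10 leading genes and the conventional DC list had 2, Cd209a and Clec10a. Cluster 4 was led by Xcr1, Tlr3 and Cadm1, which are known from DCs that cross-present antigen, and cluster 6 by Ace. The conventional DC-like share of 11.1% was 34.0% with predicted doublets kept and 34.4% with at least 300 genes per cell, a setting added after the data were seen. With at least 1000 genes and at most 5% mitochondrial UMIs it was 36.8%, and the share of cells in clusters with a Cd3d UMI in most cells was 19.3% in place of 59.0%. The monocyte-like share of 3.18% was 36.4% under that filter and 22.9% in the joint clustering. In the latter, 242 of the 278 cells of cluster 2 fell into a joint cluster named monocyte-like.

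The transcripts of the sorted proteins were compared between the libraries as a check of the gates. Il2rb, which encodes CD122 (chromosome 15, 78479256 to 78495271), was 363-fold (201 to 730) higher in the CD122+CD49a+ library, at 256 against 0.706 CPM. Itga1, which encodes CD49a (chromosome 13, 114953096 to 115101964), was 29.2-fold (18.2 to 48.9) higher there, at 41.3 against 1.41 CPM. Ly6a, which encodes Sca-1 (chromosome 15, 74994877 to 74998031), was 1.26-fold (1.13 to 1.41) higher in the LSM library, with a ratio of 1.70 (1.52 to 1.91) under TMM scaling and 1.07 for per-cell CPM averaged over cells. Itgam, which encodes the alpha chain of Mac-1 (chromosome 7, 128062640 to 128118491), gave a ratio of 1.09 (0.856 to 1.41), which spans no difference, and with TMM scaling a ratio of 1.47 (1.16 to 1.90), which does not. Ptprc, which encodes CD45 (chromosome 1, 138062861 to 138175708), was 4.20-fold (4.0 to 4.41) higher in the CD122+CD49a+ library. Both gates took CD45+ cells, so Ptprc does not check either gate. At 1500 UMIs per cell it had a UMI in 50% of LSM cluster 10 and 80.6% of CD122+CD49a+ clusters 1 and 3. In the other LSM cells the share was 34.4%, against 68.9% in CD122+CD49a+ clusters 2, 4 and 6. The cause of this difference was not tested.

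At 1500 UMIs per cell, which left out 99 LSM cells (3.31%) and 642 CD122+CD49a+ cells (52.3%), Il2rb had a UMI in 0.139% (0.0378 to 0.354) of LSM and 17.6% (14.6 to 20.9) of CD122+CD49a+ cells. Without thinning the shares were 0.335% and 29.9%. Within the thinned CD122+CD49a+ library, Il2rb had a UMI in 43.8% (37.1 to 50.7) of the cells of clusters 1 and 3 and in 0.615% (0.0746 to 2.21) of those of clusters 2, 4 and 6. Itga1 had a UMI in 2.22% (1.19 to 3.76) of thinned CD122+CD49a+ and 0.208% (0.0763 to 0.452) of thinned LSM cells, and in 6.35% and 0.737% without thinning; in the former library it was 3.84% at 1000 UMIs. Ly6a had a UMI in 16.8% (15.4 to 18.2) of thinned LSM and 14.5% (11.8 to 17.6) of thinned CD122+CD49a+ cells, in 29.4% and 18.1% without thinning, and in 12.1% and 12.6% at 1000 UMIs, where the direction turned. Itgam stood at 6.20% (5.35 to 7.14) and 4.95% (3.34 to 7.03), and at 14.3% and 5.37% without thinning. Thinning kept 217 of the 724 cells of clusters 1 and 3 and 325 of the 453 cells of clusters 2, 4 and 6, so the thinned shares of the CD122+CD49a+ library describe mostly myeloid cells. Of these kept cells, Ly6a had a UMI in 23.5% (18.0 to 29.7) of clusters 1 and 3 and 7.08% (4.54 to 10.4) of clusters 2, 4 and 6, and Itgam in 0.461% (0.0117 to 2.54) and 8.62% (5.80 to 12.2). The thinned intervals of Ly6a and of Itgam overlapped between the libraries, which holds for the cells kept only and does not compare the whole gates. A UMI of both Il2rb and Itga1 was seen in 38 of 1228 CD122+CD49a+ cells and in 0 of 2987 LSM cells.

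Within the LSM library Ly6a differed between clusters. Ly6a had a UMI in 74.1% (66.9 to 80.5) of cluster 5 cells, 71.1% (63.4 to 78.0) of the plasmacytoid DC-like cluster 7, 52.0% (37.4 to 66.3) of the stem-like cluster 13 and 45.5% (41.2 to 49.9) of the lymphoid progenitor-like cluster 2. It had a UMI in 0 of 123 mast cell and basophil-like cells of cluster 9, which allows up to 2.44%; median depth was 6977.5 UMIs in cluster 5, 4075 in cluster 7 and 1882 in cluster 9. Itgam had a UMI in 32.4% (27.4 to 37.8) of the monocyte-like cluster 4, 8.22% (6.01 to 10.9) of cluster 2 and 2 of 159 cells of cluster 7.

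**Figure D2:**
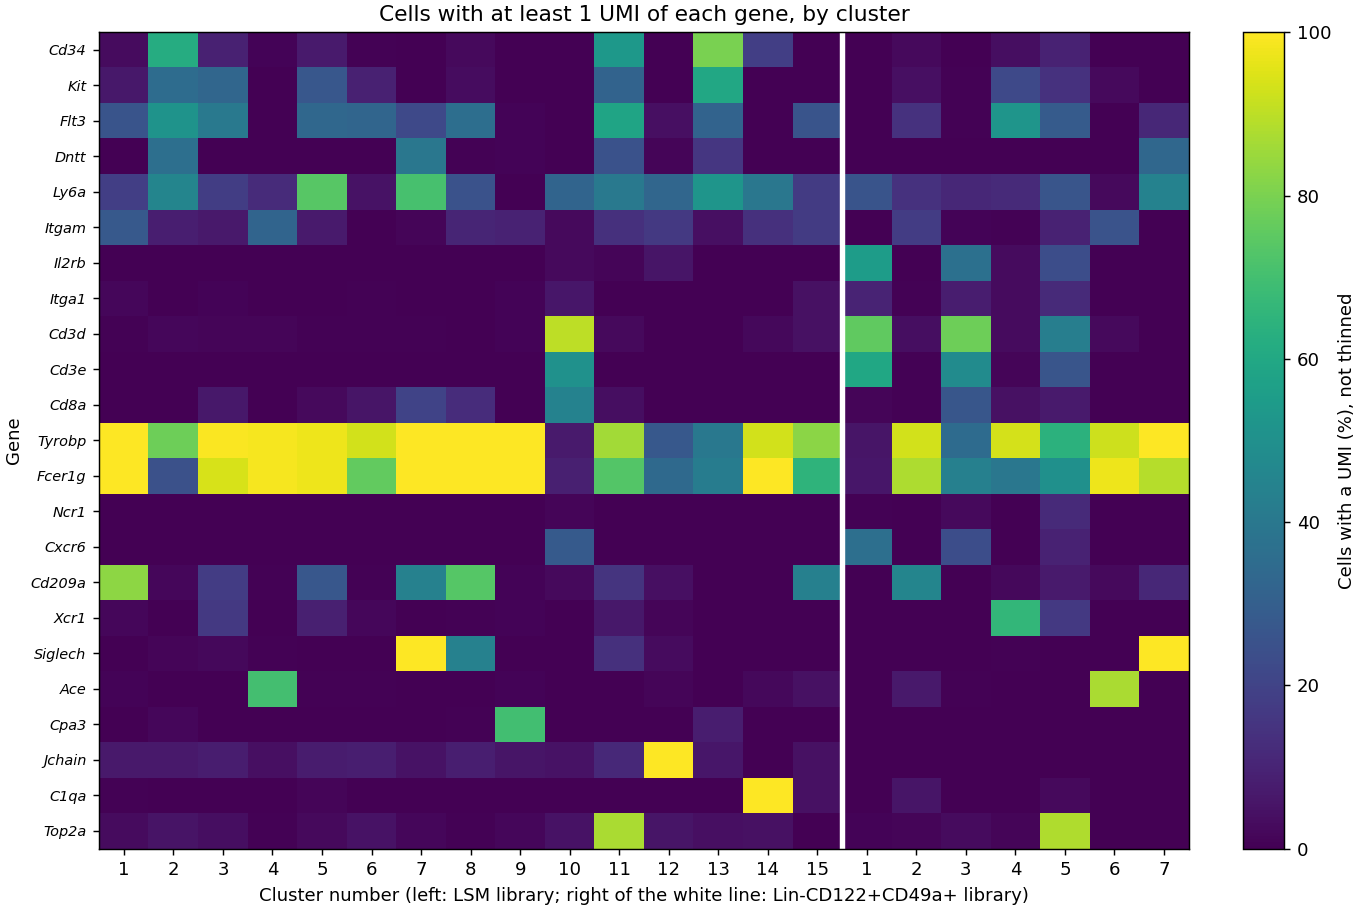
Percent of cells with at least 1 UMI (colour scale, not thinned) of the genes on the vertical axis in each cluster on the horizontal axis, LSM clusters to the left of the white line and CD122+CD49a+ clusters to the right. Cd3e stood at 59.6% in cluster 1 and 48.0% in cluster 3 of the CD122+CD49a+ library, and Cd34 at 61.8% in cluster 2 of the LSM library.

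Across all cells, the genes furthest to the LSM side included plasma cell transcripts and the chemokine genes Ccl3 and Ccl4, and those furthest to the CD122+CD49a+ side included T and innate lymphocyte transcripts. Among the 12 genes furthest to the LSM side was Jchain, the joining chain of secreted antibodies, with 46751 UMIs in the LSM library against 0. Against the floor of 3 counts in the CD122+CD49a+ library it was 2301-fold higher. The lower end of its exact interval was 1871-fold. Mzb1, an endoplasmic reticulum protein of plasma cells, was 93.1-fold (45.2 to 232) higher. The interferon-inducible membrane protein gene Ifitm1 was 21.3-fold (15 to 31.4) higher, and the chemokine genes Ccl3 and Ccl4 were 21.2-fold (17.1 to 26.7) and 20.4-fold (17.6 to 23.7) higher. The others were Ly6d, Ctsl, Tsc22d1, Ier3, Fabp5, Cox6a2 and Basp1, from 15.2-fold down to 5.44-fold.

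Among the 12 genes furthest to the CD122+CD49a+ side, the killer lectin-like receptor gene Klra7 was 403-fold (155 to 1491) higher in that library and Il2rb 363-fold. Cd160, a receptor of cytotoxic lymphocytes, was 184-fold (108 to 340) higher, Thy1 95.5-fold (72.8 to 128), the T cell kinase gene Zap70 90.6-fold (58.1 to 149) and Cd3e 81.0-fold (61.6 to 108). Gimap4, Cxcr6, Gimap3, Bcl11b, Xcl1 and Txk followed, from 66.5-fold to 35.9-fold. With no minimum CPM for the ranking, 2 of the 12 LSM genes and 3 of the 12 CD122+CD49a+ genes kept their place. The ratios compare whole libraries, which hold different mixes of cell types.

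The fixed gene lists were compared in the same way. Values are median log2 ratios of LSM over CD122+CD49a+ with the percentile among 10000 random lists, and the median of all 11365 genes with at least 20 UMIs was itself −0.31 (0.13 with TMM scaling). The killer lectin-like receptors stood at −5.41, with 10 of 11 measured members at least 2-fold higher in the CD122+CD49a+ library, such as Klra1 (−8.22) and Klrb1c (−6.12), and Klrd1 (−0.14) within 2-fold. The shared NK and ILC1 markers stood at −4.95 (9 of 10), the ILC1 markers at −4.87 (6 of 7, Cd200r1 at 0.38 being the exception) and the T cell markers at −4.31 (6 of 6). Cytotoxic effectors stood at −3.96 (8 of 8), lymphoid transcription factors at −3.61 (8 of 10, such as Tbx21 at −5.98), homing and residency receptors at −3.05 (5 of 9, with Ccr7 at 3.66 on the LSM side) and the ILC precursor markers at −2.42 (6 of 8). The percentile of each of these 8 lists was 0. Several of them share genes, such as Klrd1, Nkg7, Cxcr6 and Tcf7, so they are not separate results. NK markers stood at −2.44 (percentile 0.04) and effector cytokines and chemokines at −1.17 (0.295), with Ifng at −4.02 and Ccl3 at 4.41. With per-cell CPM averaged over cells, the killer lectin-like receptors stood at −4.38 and the NK markers at −1.68, and with members of at least 1 UMI the former stood at −4.57. Some lists hold genes of the gates: without Itga1, whose ratio was itself the ILC1 median, the ILC1 markers stood at −5.00 and the homing and residency receptors at −1.44 (percentile 0.23), and without Il2rb the shared markers stood at −4.61. The sort genes themselves stood at −2.07, the value of Ptprc, with a percentile of 0.03. Il2rb and Itga1 encode proteins that only the CD122+CD49a+ gate was sorted on, so the gates set this percentile in part. The cause of the Ptprc difference was not tested.

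On the LSM side, the plasma cell markers stood at 5.62 (4 of 4 at least 2-fold higher, 3 of them against the floor), the mast cell and basophil markers at 2.72 (7 of 7, 6 of them against the floor), the stem and multipotent progenitor markers at 2.5 (8 of 9, such as Hlf at 4.62 and Cd34 at 2.69, with 4 against the floor) and the granulocyte-monocyte progenitor markers at 2.34 (4 of 5, with 3 against the floor). Members against the floor enter these medians at their bound. The plasmacytoid DC markers stood at 1.98 (6 of 7). The percentile of each of these 5 lists was 100. B cell markers stood at 2.44 over 3 measured genes (percentile 99.88), 2 of them against the floor. These 3 genes, Cd79a, Cd79b and Ebf1, were raised in the plasma cell-like cluster 12, and no LSM cluster was named B cell-like. Kupffer cell and macrophage markers stood at 1.03 (99.8) and dissociation and immediate early genes at 1.11 (99.98), with Jun at 2.36 and Fos at 1.54. Markers of cell types outside the CD45+ gate rested on 3 to 5 measured genes, with medians of 1.93 for cholangiocytes (99.35), 1.72 for erythroid cells (99.56) and 0.83 for liver endothelium (97.15). Some of these genes were raised in CD45+ clusters of the LSM library: Epcam, whose ratio is the cholangiocyte median, in the plasma cell-like cluster 12, Car2 of the erythroid list in clusters 2 and 13, and Pecam1 and Cdh5 of the endothelial list in the plasmacytoid DC-like cluster 7. With members of at least 1 UMI, the B cell median was 0.94, the Kupffer cell and macrophage median 0.48 and the granulocyte-monocyte progenitor median 1.66. With per-cell CPM averaged over cells, the Kupffer cell and macrophage median was 1.94, the cholangiocyte median 1.09 and the erythroid median 0.88, which was 1.13 with at least 300 genes per cell.

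The lymphoid progenitor list stood at −0.25 (percentile 44.17) and at 0.19 with TMM scaling, its members going both ways, from Dntt at 5.04 to Il7r at −1.67. The other lists were MHC class II (0.02, percentile 25.68), conventional DC (0.02, 53.21), myeloid transcription factors (0.10, 58.86), interferon-stimulated genes (−0.04, 66.79, and 0.39 with TMM scaling), complement (0.48, 96.04), neutrophil (0.36, 79.53), megakaryocyte and platelet (0.70, 72.2), proliferation (−0.58, 21.04), interferon-gamma pathway (−0.70, 3.18), monocyte (−0.71, 6.32) and ILC2 (−1.40, 3.16). With per-cell CPM averaged over cells, complement stood at 1.40, megakaryocyte and platelet at 1.87 and ILC2 at −0.58, and ILC2 at −0.22 with members of at least 1 UMI. Fewer than 3 members of the ILC3, eosinophil, hepatocyte, and stellate cell and fibroblast lists reached 20 UMIs, so these lists have no median.

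**Figure D3:**
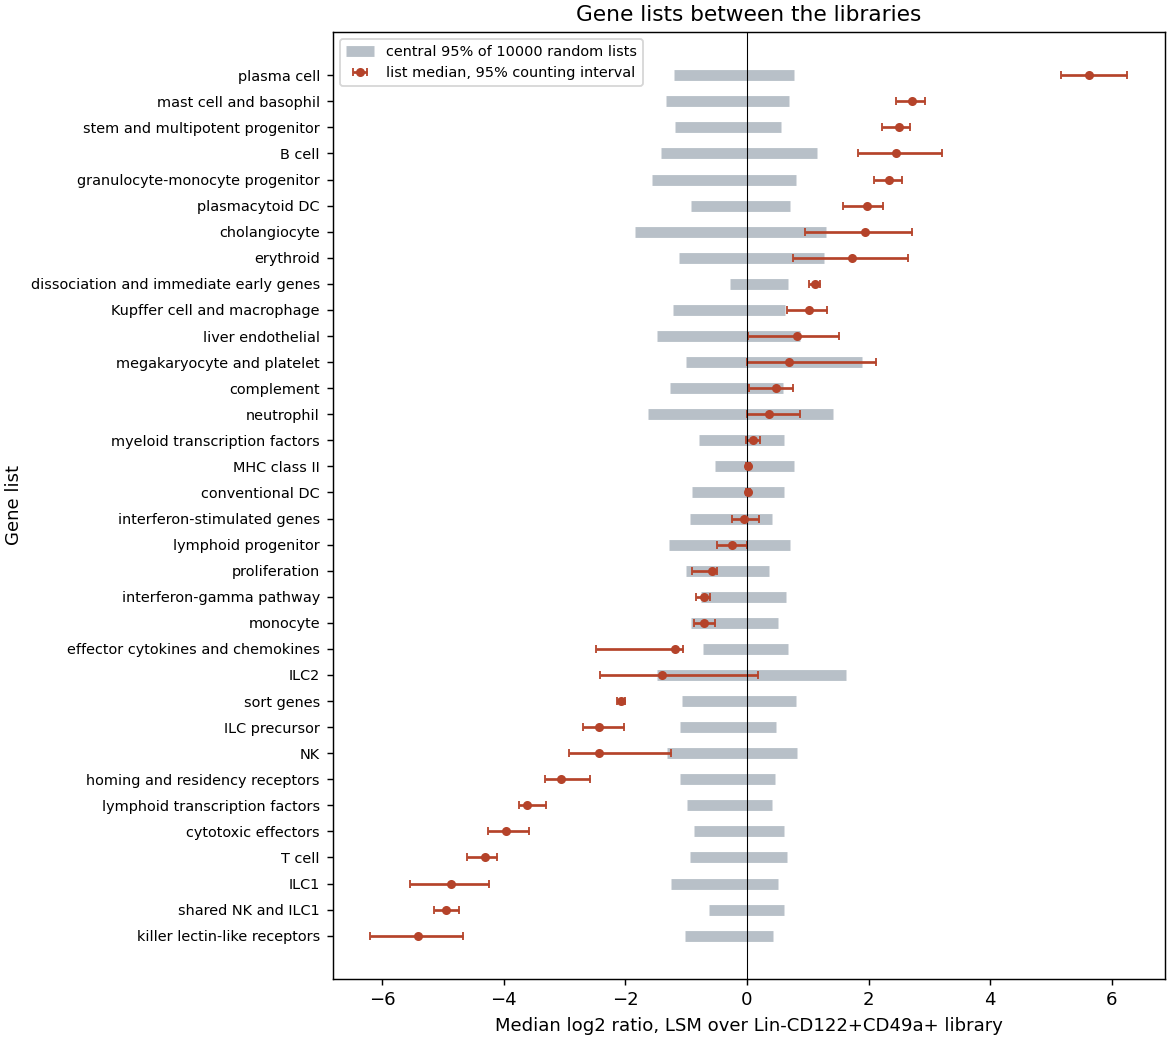
Median log2 ratio of LSM over CD122+CD49a+ summed counts (horizontal axis) for each gene list (vertical axis); red points are list medians with 95% counting intervals and grey bars the central 95% of 10000 random lists of the same size matched on mean expression. The plasma cell list lies furthest to the right at 5.62 and the killer lectin-like receptors furthest to the left at −5.41.

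The comparison of lymphocytes asked whether the LSM gate held cells like those of the CD122+CD49a+ gate. Since no ILC1-like or NK-like class was named in both libraries, clusters were compared by number, LSM cluster 10 (81 cells, 189714 UMIs) against clusters 1 and 3 of the CD122+CD49a+ library (724 cells, 1030826 UMIs). Both sets carried T cell receptor complex transcripts, with Cd3d at 1550 and 1279 CPM and Cd3g at 1576 and 1238 CPM in that order, while Cd3e, at 290 and 625 CPM, was 2.15-fold (1.63 to 2.89) higher in the CD122+CD49a+ clusters. Il2rb was 51.4-fold (14.2 to 426) higher in the CD122+CD49a+ clusters, with a UMI in 2 of 81 LSM cells and in 48.6% of the others. Il2rb encodes CD122, on which only the CD122+CD49a+ gate was sorted. Its ratio was thus set in part by the sort and does not show whether the cells are alike. Median depth was 2234 and 1258 UMIs per cell.

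Against clusters 1 and 3 together, Gzma, the granzyme A gene, was 6.14-fold (5.67 to 6.66) higher in LSM cluster 10, and Klf2, a transcription factor of circulating lymphocytes, was 7.98-fold (6.42 to 9.94) higher. The others named on that side were Tnfrsf4 (18.3-fold, 8.10 to 46.7, from 27 UMIs in 7 cells of cluster 10), Ccl4 (9.83-fold), Cx3cr1 (8.31-fold), Gzmk (7.44-fold), Zeb2 (7.31-fold) and Ass1 (6.21-fold). Gzma had a UMI in 54.3% (42.9 to 65.4) of cluster 10 and Gzmk in 19.8% (11.7 to 30.1), against 0.895% and 0.0688% of the other LSM cells. Ccl4, in contrast, had a UMI in 44.4% (33.4 to 55.9) of cluster 10 and 45.5% (43.6 to 47.3) of the other LSM cells, with 12.5% in the monocyte-like cluster 4 and 94.1% in cluster 2. In the CD122+CD49a+ library it stood at 7.60% (5.77 to 9.77) in clusters 1 and 3 and 6.40% (4.33 to 9.06) in clusters 2, 4 and 6. Klf2, Cx3cr1, Zeb2 and Ass1 also had a UMI in 71.4%, 18.9%, 28.9% and 34.3% of the other LSM cells. In clusters 2, 4 and 6 the shares were 35.8%, 15.5%, 40.2% and 8.61%. The median depth was 5142 UMIs in the other LSM cells and 2192 in clusters 2, 4 and 6. The ratios of Ccl4, Klf2 and Ass1 are not set apart here from a difference between the libraries as a whole. Zeb2 and Cx3cr1 were lower in the other LSM cells than in clusters 2, 4 and 6. Zeb2 stood at 83.0 against 340 CPM and Cx3cr1 at 61.5 against 101 CPM. This runs opposite to their ratios in the lymphocyte clusters, but the backgrounds hold different cell types. On the CD122+CD49a+ side, Fgl2 was 66.3-fold (11.8 to 2624) higher, from 1 UMI in LSM cluster 10. Fgl2 also had a UMI in 28.3% of clusters 2, 4 and 6. Bcl2, an inhibitor of cell death, was 17.9-fold (6.07 to 87.4) higher. Podnl1, Rnf225, Tnk2, Dock8 and Fam102a lay between 24.8-fold and 17.4-fold, each from 1 or 2 UMIs in LSM cluster 10, so that their intervals are wide. Dock8 also had a UMI in 19.2% of clusters 2, 4 and 6, against 14.2% of clusters 1 and 3. Each gene named on this side, Il2rb included, was also higher in clusters 2, 4 and 6 than in the other LSM cells. Some of these background values rest on few UMIs. Fgl2 stood at 176 against 57.0 CPM, Dock8 at 96.0 against 40.5 CPM and Bcl2 at 35.7 against 25.2 CPM. Part of these ratios is thus not set apart from a difference between the libraries as a whole. Of the fixed lists, Cd8a was 3.18-fold (2.31 to 4.36) and Ifng 2.34-fold (1.79 to 3.02) higher in LSM cluster 10. Klrg1 was 4.98-fold (3.01 to 8.22) higher there, and S1pr5 stood at 57.98 against 4.85 CPM. Xcl1, Cd160 and Tbx21 were higher in the CD122+CD49a+ clusters, at 764 against 111 CPM, 346 against 63.3 CPM and 127 against 26.4 CPM. Tyrobp and Fcer1g, added after the data were seen, were 14.2-fold (7.18 to 33.1) and 3.60-fold (2.46 to 5.47) higher in the CD122+CD49a+ clusters. Klra7 had 0 UMIs in LSM cluster 10 and 205 in clusters 1 and 3. At 1500 UMIs per cell, Tyrobp had a UMI in 1.52% of LSM cluster 10 and 20.3% of clusters 1 and 3. In the other LSM cells and in clusters 2, 4 and 6 the Tyrobp shares were 79.7% and 92.9%. Ncr1 had 1 UMI in LSM cluster 10 and 9.70 CPM in the CD122+CD49a+ clusters, a ratio of 0.543 (0.0125 to 3.82) that spans no difference. Clusters 1 and 3 differed in these genes, so the ratios depend on their mix. Against cluster 3 alone, a comparison added after the data were seen, Gzma was 2.59-fold (2.38 to 2.81), Klf2 4.18-fold (3.30 to 5.32) and Ifng 3.77-fold (2.63 to 5.48) higher in LSM cluster 10. The Cd8a ratio of 1.36 (0.979 to 1.87) spanned no difference, but the gene of the other CD8 chain, Cd8b1, was 2.01-fold (1.62 to 2.49) higher in LSM cluster 10, and 4.79-fold (3.88 to 5.91) higher there than in clusters 1 and 3. The other genes named on the LSM side lay between 3.49-fold and 19.4-fold. Il2rb was 30.5-fold (8.27 to 254), Fgl2 45.6-fold (7.99 to 1818) and Tbx21 2.79-fold (1.07 to 9.21) higher in cluster 3, where Bcl2 stood at 167 against 15.8 CPM. The Podnl1 ratio of LSM over cluster 3 was 0.358 (0.00779 to 2.95), which spans no difference. Of the 8 genes named per direction, 3 on each side kept their place. The clusters were picked by their leading genes, which include Gzma and Il2rb, so the ratios of these genes partly restate the clustering. The Il2rb ratios also partly restate the sort on CD122. The dissociation and immediate early genes were also higher in LSM cluster 10, at 4559 CPM (4261 to 4873). They summed to 3108 CPM (2972 to 3250) in cluster 1 and 2243 CPM (2100 to 2393) in cluster 3 of the CD122+CD49a+ library. Whether this bears on the ratios was not tested.

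Clustered jointly, 77 of the 81 cells of LSM cluster 10 fell into joint cluster 6, led by Gzma, Gzmb and Ccl5, which also took 250 of the 256 cells of CD122+CD49a+ cluster 3. LSM cluster 10 and CD122+CD49a+ cluster 3 still differed in genes such as Tyrobp, at 42.2 and 1417 CPM in that order. Joint cluster 3, led by Il2rb, Gimap3 and Gimap4, held 451 CD122+CD49a+ and 4 LSM cells. Joint clusters 3 and 6 both passed the naming rule as T cell-like. The progenitor clusters 2 and 13 of the LSM library fell whole into joint cluster 1, which held 575 LSM cells and 0 cells of the CD122+CD49a+ library. LSM cluster 3 and CD122+CD49a+ cluster 4, which shared leading genes such as Rab7b and Ppt1, fell mainly into different joint clusters. Joint cluster 4 held 396 LSM and 13 CD122+CD49a+ cells, and joint cluster 12 held 3 and 124. LSM cluster 1 and CD122+CD49a+ cluster 2, both led by Cd209a, also parted, mainly into joint clusters 2 and 8. With 1 library per gate, a joint cluster drawn mostly from 1 library may reflect that library. This holds for joint clusters 1 and 3 too.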

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

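The gene minimum of 300, the comparison with cluster 3 alone and the lists without sort genes were chosen after the data were seen, and the other settings before. No paired analysis was possible because each group has 1 library. Of 207 list medians under alternatives, 203 kept their sign; the lymphoid progenitor and interferon-stimulated lists changed it with TMM scaling, and the lymphoid progenitor and neutrophil lists stood at 0 with members of at least 1 UMI. With TMM scaling the median of the T cell list was −3.88, of conventional DC 0.46, of lymphoid progenitor 0.19 and of stem and multipotent progenitor 2.94, each moved by the same factor. With per-cell CPM averaged over cells, the T cell list stood at −3.95 and lymphoid progenitor at −0.56, and with members of at least 1 UMI the stem list stood at 2.10. With no minimum CPM, 2 and 3 of the 12 named genes per direction were kept, since genes of few counts enter the ranking. Against cluster 3 of the CD122+CD49a+ library alone, 3 of the 8 named lymphocyte genes per direction were kept. The stricter cell filter gave 0.973% T cell-like (and Cd3d-positive cluster) cells, 16.5% conventional DC-like, 20.4% lymphoid progenitor-like, 6.89% monocyte-like and 0.856% Kupffer cell and macrophage-like cells in the LSM library. In the CD122+CD49a+ library it gave 19.3% in Cd3d-positive clusters, 36.8% conventional DC-like and 36.4% monocyte-like. The joint clustering gave 12.3% monocyte-like and 9.61% plasmacytoid DC-like LSM cells and 22.9% monocyte-like CD122+CD49a+ cells. The conventional DC-like share of LSM cells was 23.6% with doublets kept, 30.1% and 5.46% at Leiden resolutions 0.3 and 1.0, 23.9% without cell cycle genes and 22.8% in the joint clustering; in the CD122+CD49a+ library it was 34.0% with doublets kept, 13.2% at resolution 0.3 and 34.4% with 300 genes. At resolution 1.0 the LSM share equalled that of cluster 6 alone (163 cells). In the joint clustering, joint cluster 8, named monocyte-like, took 242 of the 278 cells of unnamed CD122+CD49a+ cluster 2. Joint cluster 11, named plasmacytoid DC-like, took 126 of the 152 cells of unnamed LSM cluster 8. The joint shares of 22.9% and 9.61% thus moved mainly because cells of unnamed clusters took a name. The cause of the other changes was not tested. Neither progenitor cluster had a name at resolution 0.3 or jointly, so no share is given there; the same holds for mast cell and basophil-like LSM cells under the stricter filter, and for plasmacytoid DC-like CD122+CD49a+ cells under that filter and at resolution 0.3. Shares of cells with a UMI moved with the thinning depth, which also sets how many cells are left out: Ly6a had 12.1% at 1000 UMIs and 29.4% unthinned in LSM cells and 12.6% and 18.1% in CD122+CD49a+ cells, and Il2rb 21.5% at 1000 UMIs and 29.9% unthinned in the latter.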

Other observations

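The second clustering and all tests on CD3 transcripts and on myeloid cells were chosen after the result was seen, and the tests on Ly6a before it, once the high Ly6a and interferon-stimulated levels of cluster 5 were known. Clusters 1 and 3 of the CD122+CD49a+ library, clustered again on their own, gave 3 subclusters. Subcluster 1 (452 cells, 62.4% of the 724) was led by Maf, Serpina3g and Ccnd2, and subcluster 2 (188 cells, 26.0%) by Cd8b1, Lgals3 and Ly6c2. Subcluster 3 (84 cells, 11.6%) was led by Tyrobp, Lat2, Fcer1g, Klra3 and Gzmb. Zbtb16, which encodes the PLZF factor of innate-like T cells and ILC precursors, had a UMI in 7.52% (5.27 to 10.4) of subcluster 1, 1 of 188 cells of subcluster 2 and 0 of 84 cells of subcluster 3, which allows up to 3.57%. Itga1 had a UMI in 16.7% (9.42 to 26.4) of subcluster 3 and 9.73% (7.16 to 12.8) of subcluster 1. In clusters 2, 4 and 6, taken as background, Zbtb16 had a UMI in 2 and Itga1 in 6 of 453 cells, at a median depth of 2192 UMIs against 1186 in subcluster 1 and 1313 in subcluster 3.

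CD3 transcripts were present in most lymphocytes of the CD122+CD49a+ library. Free RNA as their source is argued against by Cd3e UMIs in 0.883% of the cells of clusters 2, 4 and 6 and in 55.5% (51.8 to 59.2) of those of clusters 1 and 3, and doublets with myeloid cells by the median UMI count of clusters 1 and 3, which was 0.574 times that of clusters 2, 4 and 6. A UMI of Tyrobp or Fcer1g, known from NK cells and ILC1, was seen in 10.6% (7.93 to 13.8) of subcluster 1 and 90.5% (82.1 to 95.8) of subcluster 3, but both genes lead subcluster 3, so the clustering set this contrast, and for subcluster 1 ILC1 or NK cells that carry CD3 transcripts cannot be told apart from T cells. In subcluster 3 a Cd3e UMI in 41.7% (31.0 to 52.9) of cells argues against a set made up of ILC1 or NK cells without Cd3e transcripts, while a mixture stays open. As a hypothesis, T or natural killer T cells with CD122 may make up part of cluster 1, which stays open; the antibodies of the lineage panel and T cell receptor genes were not analysed here.

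Myeloid cells of the CD122+CD49a+ library (clusters 2, 4 and 6) had few UMIs of Il2rb and Itga1. At 1500 UMIs, Il2rb had a UMI in 0.615% of these cells and 43.8% of clusters 1 and 3. Il2rb is a leading gene of cluster 1, so the clustering partly set this contrast, and it does not decide on low depth. For Itga1, 0.508% (0.0615 to 1.82) and 6.11% (4.29 to 8.39) at 1000 UMIs argue against low depth hiding a level like that of clusters 1 and 3. At 1500 UMIs, with fewer cells, the Itga1 intervals overlapped (0.615% and 3.69%). A lower level of either gene may still be missed at these depths. Reads of the LSM library assigned to the wrong library are argued against by the barcodes, since 0 of the 453 cells had a barcode of the LSM library. Cells outside the gate carried through the sort, 36.9% (34.2 to 39.7) of the library, cannot be told apart from cells stained on the surface without transcripts, because no purity record of the sort was used here. No biological explanation was tested.

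Ly6a and interferon-stimulated genes were raised in the same cells of clusters 1, 3 and 8 of the LSM library. If cells thinned to 1500 UMIs are split by a Ly6a UMI, those with 1 or more (110 cells) had 3.76 times (3.18 to 4.44) the interferon-stimulated UMIs of those without (1054 cells), which argues against deeper cells showing both genes. Dissociation as the cause is argued against by the immediate early genes, which stood at 0.851 times (0.794 to 0.911). An interferon response may raise Ly6a: the ratio was above 1 in all 3 clusters. The lowest was 2.21 (1.22 to 3.74) in cluster 3, from 16 interferon-stimulated UMIs in 24 cells with Ly6a. Without thinning it was 1.38 (1.16 to 1.65) there. Cells close to the interferon-rich cluster 5 that were placed in these clusters stay open as a source, as the split does not tell a response within a cell type from a mixture, and with 1 library there is no replicate check. Other clusters were not split by Ly6a. Clusters 7 and 13 also had Ly6a in many cells. Their interferon-stimulated genes summed to 544 CPM (489 to 603) and 230 CPM (178 to 294), against 555 CPM (531 to 580) in cluster 1.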
